A study of Mus musculus with 48 samples.

How the data were processed

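Gene expression was measured in organoids grown from mouse submandibular salivary glands, irradiated with photons or protons on day 5 of culture. RNA with an integrity number above 9 per the labels, 100 ng per library, went into QuantSeq 3' libraries, which sequence the ends of polyadenylated transcripts. The deposited count files hold, per gene, the number of reads the authors assigned to it, with no normalization. Per the submitters' processing notes the genome build was GRCm39 and edgeR was among the tools. The aligner, the counting program, its strand setting and the annotation version are not given in the sources used here. No coordinates are printed, because the reference used here is of another build, GRCm38.

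Each count file listed 47643 gene identifiers and 5 summary lines for reads not assigned to a gene. The summary lines were left out of library sizes and tests, and reads outside genes made up 7.88 to 12.1% of a library. Symbols came from the reference table for 47224 identifiers, 419 had none, and 120 identifiers shared a symbol. The 4 deposited CPM tables were not used. All 48 libraries were assigned to 16 groups of 3 by their titles. Per the labels, same-numbered samples within a radiation type came from the same animal, a pairing the main tests did not use. Deviations from the group means, over 9709 genes, had a mean correlation between same-numbered libraries of 0.07, 0.072, 0.07 and -0.028 for photons at days 2 and 6 and protons at days 2 and 6. Between other libraries it was -0.038, -0.033, -0.034 and 0.014. The labels do not settle whether the same 3 mice served both radiation types. No pair of replicates agreed within sampling noise, so each was counted once.

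Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter and the quasi-likelihood F test. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Each radiation type and day was fitted with its 12 libraries, so that the doses shared an estimate of the spread. Each dose was set against the control of the same type and day, and 15 Gy against 4 Gy. Differences between proton and photon effects, and between days, came from interaction contrasts in fits of 24 libraries. In all 26 comparisons were made. SE is the log2 fold change divided by the square root of F. Genes tested numbered 11039, 11308, 10529 and 10810 in the fits of photons at days 2 and 6 and protons at days 2 and 6. The design, the tests of these comparisons, the gene lists and the alternatives, apart from the added ones named here, were fixed before the data were examined. Tests of explanations were in part chosen later.

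The 30 lists were p53 targets, DNA replication and S phase, G2 and mitosis, cyclin-dependent kinase inhibitors, nuclear proteins lost in senescence, type I interferon-stimulated genes, nucleic acid sensing, MHC class I presentation, inflammatory and senescence-associated secreted factors, homologous recombination and Fanconi anaemia, and non-homologous end joining. Cell type lists covered acinar, luminal duct, granular duct, basal duct, myoepithelial, fibroblast, endothelial and immune cells. The others were squamous and keratinization genes, stem cell and Wnt targets, YAP targets, TGF-beta response and matrix, cholesterol synthesis, NRF2, ATF4, hypoxia and glycolysis, immediate early, heat shock and mitochondrially encoded genes. Lists were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and with an estimated correlation. Of 681 list tests, 267 passed with the preset and 72 of those also with the estimated correlation. A camera p printed without a value for the estimated correlation either passed both ways or passed neither.

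Named genes followed a fixed rule. For each radiation type and day the rule took the 5 highest and 5 lowest log2 fold changes at 15 Gy past the threshold, with a mean of at least 5 CPM, the same sign in all 3 mice and a named symbol. It added up to 4 members of each list with the smallest p, and Cdkn1a, Mdm2, Mki67, Lmnb1, Isg15, Ifit1, Ifnb1, Aqp5, Krt14 and Acta2 wherever measured. For other comparisons it took the 5 highest and 5 lowest. The rule gave 389 calls. The text names mainly those whose call held with each library left out, a choice made after the values were seen, so the stability of the named genes does not speak for the other calls. Ltf and Cybb, Gsdmc and Lypd5 are among the extremes the rule took in the controls. Some genes the rule took are not reported here. A gene's value was taken to move when its log2 value changed by over 1.5 times.

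Depth ran from 314409 to 4745719 counts per library. On simulated counts with 200 changed genes at 15 Gy, the test recovered 52% of log2 changes of 1 for photons at day 2, 78% at day 6, 62% for protons at day 2 and 60% at day 6. At a log2 change of 2 it recovered 95, 98, 96 and 92%. The simulated data do not carry batch effects. Intervals and floors cover counting error only; the floor was 3 counts over a group.

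Alternatives were DESeq2's size factors in edgeR, library size alone, DESeq2 1.42.0, no low-count filter, a filter of 5 CPM in 3 libraries, the replicate number as a block, all 48 libraries in a single fit and each library left out. Leaving out both libraries that stand apart, the photon control of day 2, mouse 3, and 4 Gy of photons, day 6, mouse 3, was added after seeing the data. Photons and protons were given on different days, and the day cannot be told apart from the radiation type, so the proton and photon series were compared by differences of effects, and their levels only for 1 test of the interferon list.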

Results

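Organoids are small epithelial structures grown from tissue cells in a gel. Those analysed here were grown from the submandibular salivary glands, a pair of large saliva-producing glands, of C57BL/6 mice aged 8 to 12 weeks. Organoids in Matrigel, a basement membrane gel, were irradiated on day 5 of culture with photons or with protons at 4, 7 or 15 Gy, or left unirradiated, and RNA was collected 2 or 6 days later. The 2 radiation types, 2 days and 4 dose levels gave 16 groups of 3 libraries, numbered by mouse, 48 libraries in all. QuantSeq counted the 3' ends of messenger RNAs, so a count stands for a transcript end whatever the transcript's length. Photons and protons were given on different days, each with its own controls. A level in proton-irradiated organoids is therefore not compared with one in photon-irradiated organoids directly, only the change from the matching control.

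Gene counts ran from 314409 to 4745719 per library, with a median of 2952939. The lowest total belonged to the library of 4 Gy of photons, day 6, mouse 3, and the next lowest held 1311666 counts. Unirradiated organoids of the proton series held 1812349 to 2244980 counts at day 6, with TMM factors of 0.895 to 0.946 against 0.965 to 1 at day 2, and all irradiated groups of that day held more, 2514472 to 4220561, with factors of 0.96 to 1.08. At day 2 the groups of 4 and 7 Gy of photons held 3317479 to 3951771 counts against 2154261 to 3279316 in their controls. Between 10904 and 16516 genes had a count in a library. Mitochondrial transcripts took 4.09 to 11.4% of the counts, with 7.66 to 8.31% at 4 Gy of protons, day 2, against 8.87 to 9.48% in its controls. The photon control of day 2, mouse 3, stood apart from the other controls of its group on the second principal component of the counts. Parentheses after a gene hold its identifier at first mention and its log2 fold change ± standard error (SE), from 3 libraries in each group; a list's median is the median log2 fold change of its measured members. CPM is a count scaled to a common library total. Ratios against a group with 3 counts or fewer carry an interval for counting error only.

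**Figure D1:**
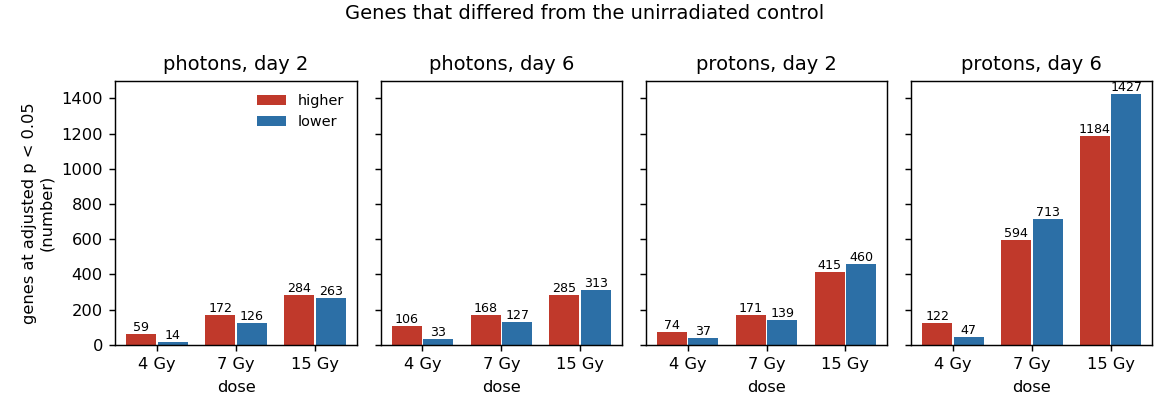
Number of genes (vertical axis, from 0) at an adjusted p under 0.05 by dose (horizontal axis, Gy) for each radiation type and day, 3 irradiated libraries against 3 controls, with red bars for higher and blue bars for lower genes. Protons at 15 Gy, day 6, had the most, 1184 higher and 1427 lower.

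The first question was what photons changed within 2 days. At 15 Gy, genes that type I interferons switch on rose together: 34 of 35 measured members of that list rose, with a median of 3.55. Among them were Ifit1 (ENSMUSG00000034459, 5.35 ± 0.30), which holds back translation of foreign RNA, Rsad2 (ENSMUSG00000020641, 5.56 ± 0.33), an antiviral enzyme, Isg15 (ENSMUSG00000035692, 4.53 ± 0.36), a ubiquitin-like protein, and Usp18 (ENSMUSG00000030107, 4.32 ± 0.26), which strips it from its targets. Near-absent in the controls, Ifit3 (ENSMUSG00000074896, 290-fold, counting interval 51.6 to 1.15e+04), Ifit3b (ENSMUSG00000062488, 149-fold, counting interval 40.9 to 1.23e+03) and Mx2 (ENSMUSG00000023341, 101-fold, counting interval 17.8 to 4.04e+03) were also higher. Genes that load peptides onto MHC class I had a median of 0.76, and 4 of 13 rose, led by the peptide transporter Tap1 (ENSMUSG00000037321, 1.61 ± 0.16). Targets of p53 rose in 10 of 40 cases and fell in 1. Higher were Mdm2 (ENSMUSG00000020184, 1.26 ± 0.17), the ligase that degrades p53, Cdkn1a (ENSMUSG00000023067, 0.95 ± 0.17), the cell cycle inhibitor p21, Bbc3 (ENSMUSG00000002083, 0.81 ± 0.13), which promotes cell death, Ccng1 (ENSMUSG00000020326, 1.04 ± 0.12) and Ak1 (ENSMUSG00000026817, 1.25 ± 0.16). Of 13 genes that sense nucleic acids 2 rose, Ifi204 (ENSMUSG00000073489, 2.35 ± 0.29) and Tlr3 (ENSMUSG00000031639, 1.01 ± 0.19). Far lower were the protease inhibitors Serpina3m (ENSMUSG00000079012, -3.49 ± 0.34) and Serpina3n (ENSMUSG00000021091, -2.84 ± 0.43), the tubulin-binding Tppp (ENSMUSG00000021573, -2.96 ± 0.52), the lipid carrier Apoe (ENSMUSG00000002985, -2.76 ± 0.33) and the basement membrane collagen Col4a4 (ENSMUSG00000067158, -2.53 ± 0.43). The transcription factor subunit Jun (ENSMUSG00000052684, -1.68 ± 0.27), the duct regulator Tfcp2l1 (ENSMUSG00000026380, -1.06 ± 0.11), the hemidesmosome gene Dst (ENSMUSG00000026131, -1.08 ± 0.14) and the keratin Krt10 (ENSMUSG00000019761, -1.91 ± 0.31) were lower, while Chrm3 (ENSMUSG00000046159, 1.35 ± 0.23), the muscarinic receptor that drives saliva secretion, was higher. Hypoxia and glycolysis genes had a median of -0.90, and 9 of 16 fell.

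Each gene just named had an adjusted p of 0.00583 or less by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and of 11039 genes tested 284 rose and 263 fell. Adjusted over the list alone, 35 interferon, 8 MHC class I and 19 p53 genes were called. Their camera adjusted p was 1.5e-171, 5.5e-09 and 5.5e-09 with the preset. With an estimated correlation it was 0.001, 0.015 and 0.0013. For the hypoxia list, 12 were called adjusted over the list alone (camera adjusted p = 5.5e-09, adjusted p = 0.14 with an estimated correlation). For the sensing genes, 4 were called adjusted over the list alone (camera adjusted p = 0.017, adjusted p = 0.089 with an estimated correlation). Total calls came to 252 without 15 Gy mouse 1, 304 without control mouse 2, 306 without 15 Gy mouse 3 and 1292 without control mouse 3. The p53 count was 6 without 15 Gy mouse 3. The p53 targets that fell numbered 0 without control mouse 1 or 2, 4 Gy mouse 1, 2 or 3, 7 Gy mouse 2 or 3 or 15 Gy mouse 1 or 2. The MHC class I count was 1 without 15 Gy mouse 1, 2 without 15 Gy mouse 3 and 7 without control mouse 1. The hypoxia count was 0 without 15 Gy mouse 1, 1 without control mouse 2 or 15 Gy mouse 3, 3 without 7 Gy mouse 3, 4 without 4 Gy mouse 3 and 5 without 7 Gy mouse 2.

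Lower photon doses were compared with the same day 2 controls. At 4 Gy interferon-stimulated genes rose in 25 of 35 (31 adjusted over the list alone, median 2.02; camera adjusted p = 1.3e-114), among them Ifit1 (3.83 ± 0.31) and Isg15 (3.34 ± 0.36). At 7 Gy they rose in 32 of 35 (34 adjusted over the list alone, median 2.96; camera adjusted p = 1.7e-149), with Ifit1 (4.85 ± 0.30) and Isg15 (4.20 ± 0.36). At 4 Gy, 3 of 40 p53 targets rose (10 adjusted over the list alone, median 0.38; camera adjusted p = 5.7e-08). At 7 Gy, 7 of 40 (15 adjusted over the list alone; camera adjusted p = 9.5e-07) of them rose. By edgeR's quasi-likelihood test, 59 genes rose and 14 fell at 4 Gy, and 172 rose and 126 fell at 7 Gy. The 4 Gy split was 61 higher and 6 lower with library size alone and 82 higher and 34 lower with DESeq2. The total at 4 Gy was 23 without 4 Gy mouse 3, 30 without 4 Gy mouse 1, 35 without control mouse 2, 46 without 7 Gy mouse 2 and 172 without control mouse 1. The interferon count there was 15 without 4 Gy mouse 3 and 16 without control mouse 2. Calls at 7 Gy numbered 132 without 7 Gy mouse 1, 144 without 7 Gy mouse 2, 159 without 7 Gy mouse 3, 166 without control mouse 2 and 685 without control mouse 1. The p53 count was 0 without control mouse 2 or 4 Gy mouse 1 or 3 and 5 without control mouse 1 at 4 Gy and 2 without 7 Gy mouse 1 or 3 and 4 without control mouse 2 or 7 Gy mouse 2 at 7 Gy.

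Did the response grow between 4 and 15 Gy of photons? At day 2, interferon-stimulated genes were higher at 15 Gy, with 15 of 35 members called, 20 with the replicate block, and a median of 1.32 (33 adjusted over the list alone; camera adjusted p = 2.2e-83). Targets of p53 had a median of 0.07 (-0.01 with library size alone) and MHC class I genes one of 0.35 (camera adjusted p = 0.0011, adjusted p = 0.15 with an estimated correlation). EdgeR's quasi-likelihood test called 26 genes higher and 3 lower, 5 and 2 with library size alone, 58 and 17 with DESeq2. All calls came to 0 without 4 Gy mouse 1 or 3, 1 without 15 Gy mouse 1, 2 without 4 Gy mouse 2, 3 without 15 Gy mouse 3, 5 without 7 Gy mouse 2 and 88 without control mouse 3. The interferon count was 0 without 4 Gy mouse 1 or 3, 1 without 15 Gy mouse 1, 2 without 4 Gy mouse 2, 3 without 15 Gy mouse 3, 5 without 7 Gy mouse 2 and 26 without control mouse 3.

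The second question was what remained different 6 days after photons. At 15 Gy, 37 of 40 interferon-stimulated genes rose, with a median of 2.59, among them Ifit1 (3.50 ± 0.37) and Isg15 (2.74 ± 0.43) and Trim30a (ENSMUSG00000030921, 4.44 ± 0.41). The synthetase-like gene Oasl2 (ENSMUSG00000029561, 2.99 ± 0.20), the transcription factor Irf7 (ENSMUSG00000025498, 2.97 ± 0.25) and Bst2 (ENSMUSG00000046718, 2.85 ± 0.24), which tethers virus particles to the cell surface, were also higher. MHC class I genes rose in 9 of 14 cases, including the heavy chain H2-D1 (ENSMUSG00000073411, 1.72 ± 0.22), the proteasome subunit Psmb8 (ENSMUSG00000024338, 1.88 ± 0.27) and Tap1 (1.44 ± 0.14), and the chemokine Ccl5 (ENSMUSG00000035042, 2.80 ± 0.40) was higher. Genes of squamous differentiation fell in 11 of 15 cases, with a median of -1.81. Krt13 (ENSMUSG00000044041, -2.84 ± 0.22), Krt6b (ENSMUSG00000023041, -2.81 ± 0.31) and Krt16 (ENSMUSG00000053797, -3.25 ± 0.47), keratins of stratified epithelium, were among them. The cornified envelope gene Cnfn (ENSMUSG00000063651, -3.52 ± 0.42) and Krtdap (ENSMUSG00000074199, -3.39 ± 0.39) fell too, as did Dapl1 (ENSMUSG00000026989, -3.12 ± 0.31) and the Notch target Hey1 (ENSMUSG00000040289, -2.85 ± 0.34) outside the list. Cholesterol synthesis fell in 13 of 18 genes (median -0.88), among them the enzymes Cyp51 (ENSMUSG00000001467, -1.37 ± 0.18), Lss (ENSMUSG00000033105, -1.10 ± 0.21) and Nsdhl (ENSMUSG00000031349, -1.09 ± 0.21). Targets of p53 rose in 15 of 40 cases, including Mdm2 (1.25 ± 0.19), Ccng1 (1.09 ± 0.14) and Ak1 (1.28 ± 0.13) and the noncoding Pvt1 (ENSMUSG00000097039, 1.23 ± 0.20). Hypoxia and glycolysis genes fell in 7 of 16 cases (median -0.72), with the oxygen sensor Egln3 (ENSMUSG00000035105, -1.54 ± 0.28) and Ndrg1 (ENSMUSG00000005125, -1.50 ± 0.27) as examples. Ifi204 (2.17 ± 0.28) and Tlr3 (1.02 ± 0.15) were again higher, and the matrix gene Tnc (ENSMUSG00000028364, -0.84 ± 0.13) was lower.

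Each of these genes had an adjusted p of 0.00589 or less by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment; of 11308 genes tested, 285 rose and 313 fell. Mki67 (ENSMUSG00000031004, -1.61 ± 0.32), a marker of dividing cells, fell (adjusted p = 0.00786 by the same test, 0.065 without control mouse 1). Adjusted over the list alone, 40 interferon, 11 MHC class I, 12 squamous, 17 cholesterol and 20 p53 genes passed. Their camera adjusted p was 1.9e-97, 1.7e-19, 8.5e-22, 1.7e-19 and 7.5e-14 with the preset. With an estimated correlation it was 0.0048, 0.014, 0.0011, 0.009 and 0.00047. In the hypoxia list, 12 passed adjusted over the list alone (camera adjusted p = 3e-08, adjusted p = 0.2 with an estimated correlation). Total calls came to 271 without 15 Gy mouse 2, 364 without control mouse 1, 378 without 15 Gy mouse 1 and 1025 without 4 Gy mouse 3. Called p53 genes numbered 7 without 15 Gy mouse 2 and 9 without control mouse 1 or 15 Gy mouse 1 or 3. The cholesterol count was 8 without 15 Gy mouse 1 or 2. Called MHC class I genes numbered 5 without 15 Gy mouse 2. Called hypoxia genes numbered 2 without 15 Gy mouse 2 and 4 without control mouse 3 or 15 Gy mouse 3.

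At the lower photon doses of day 6, interferon-stimulated genes rose in 29 of 40 (39 adjusted over the list alone, median 2.26; camera adjusted p = 9.6e-131) at 4 Gy. At 7 Gy the count was 35 of 40 (39 adjusted over the list alone, median 2.46; camera adjusted p = 1.1e-128). Ifit1 (3.03 ± 0.37) rose at 4 Gy, and Ifit1 (3.44 ± 0.37), Isg15 (2.83 ± 0.43) and Mdm2 (1.08 ± 0.19) at 7 Gy. Squamous genes fell in 6 of 15 (10 adjusted over the list alone; camera adjusted p = 9.8e-16) at 4 Gy. They fell in 10 of 15 (12 adjusted over the list alone; camera adjusted p = 4.6e-23) at 7 Gy. By edgeR's quasi-likelihood test, 106 genes rose and 33 fell at 4 Gy, 168 rose and 127 fell at 7 Gy. The total at 4 Gy was 63 without 4 Gy mouse 2, 88 without 4 Gy mouse 1 and 91 without control mouse 2. Calls at 7 Gy numbered 166 without 7 Gy mouse 2, 169 without 7 Gy mouse 1, 191 without control mouse 2, 193 without control mouse 1 and 495 without 4 Gy mouse 3. The squamous count at 4 Gy was 2 without 4 Gy mouse 2 and 3 without control mouse 2 or 3.

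Between 4 and 15 Gy of photons at day 6, 2 of 30 genes of G2 and mitosis and 0 of 32 S phase genes were lower, with medians of -1.33 (29 adjusted over the list alone; camera adjusted p = 5.3e-37, adjusted p = 0.063 with an estimated correlation) and -0.74 (18 adjusted over the list alone; camera adjusted p = 5.3e-20, adjusted p = 0.063 with an estimated correlation). The mitotic count was 0 without control mouse 1 or 2, 4 Gy mouse 1 or 2, 7 Gy mouse 2 or 15 Gy mouse 1, 2 or 3, 1 without control mouse 3, 6 without 7 Gy mouse 1, 10 without 4 Gy mouse 3 and 13 without 7 Gy mouse 3, 1 with the replicate block, and that of S phase 2 without 4 Gy mouse 3 and 4 without 7 Gy mouse 3. Against control, the median of the mitotic genes was 0.68 (0 higher, 6 adjusted over the list alone; camera adjusted p = 1.2e-09, adjusted p = 0.54 with an estimated correlation) at 4 Gy and -0.55 (2 lower, 2 adjusted over the list alone; camera adjusted p = 5.7e-06, adjusted p = 0.43 with an estimated correlation) at 15 Gy. The count was 1 without 4 Gy mouse 3 or 7 Gy mouse 3 at 4 Gy, and 0 without control mouse 1, 1 without control mouse 2 or 15 Gy mouse 1 or 2 and 5 without 7 Gy mouse 3 at 15 Gy. Over all 11308 genes, no gene was called higher and 16 were called lower by edgeR's quasi-likelihood test, with 951 genes at an unadjusted p under 0.05 and 0 higher and 51 lower by DESeq2. All calls came to 1 without 15 Gy mouse 1 or 2, 2 without 4 Gy mouse 1 or 2, 3 without control mouse 1, 4 without 7 Gy mouse 2, 6 without control mouse 2, 7 without control mouse 3 or 15 Gy mouse 3, 60 without 7 Gy mouse 3 and 64 without 4 Gy mouse 3. Interferon-stimulated genes had a median of 0.26 (0 adjusted over the list alone; camera adjusted p = 0.00054, adjusted p = 0.45 with an estimated correlation).

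Protons were asked the same questions against their own controls. By day 2 after 15 Gy, 29 of 35 interferon-stimulated genes rose, with a median of 2.13. Ifit1 (4.77 ± 0.52), Isg15 (3.12 ± 0.52) and Usp18 (3.26 ± 0.38) rose, as did the chaperone Rtp4 (ENSMUSG00000033355, 3.38 ± 0.35) and the chemokine Cxcl10 (ENSMUSG00000034855, 4.45 ± 0.55). Among the sensors Ifi204 (1.42 ± 0.20) was higher. Without a count in the controls, Ifit3b (at least 25.8-fold) was higher, as was Ccl5 (31.5-fold, counting interval 5.33 to 1.27e+03) from 1 control count. Targets of p53 rose in 8 of 40 cases, led by Mdm2 (1.06 ± 0.13), Ccng1 (0.87 ± 0.12), Ei24 (ENSMUSG00000062762, 0.90 ± 0.16) and Ak1 (0.72 ± 0.14). Among kinase inhibitors Cdkn1a (0.66 ± 0.14) and Cdkn2b (ENSMUSG00000073802, 0.76 ± 0.15) rose while Cdkn1b (ENSMUSG00000003031, -0.65 ± 0.14) fell. Hypoxia and glycolysis genes fell in 11 of 16 cases (median -0.91), including Ndrg1 (-1.67 ± 0.15) and Egln3 (-1.18 ± 0.15), the collagen hydroxylase P4ha1 (ENSMUSG00000019916, -1.14 ± 0.15) and the glucose carrier Slc2a1 (ENSMUSG00000028645, -0.99 ± 0.14). The immediate early genes Jun (-1.21 ± 0.13), Egr1 (ENSMUSG00000038418, -1.43 ± 0.20), Ier2 (ENSMUSG00000053560, -1.14 ± 0.21) and Zfp36 (ENSMUSG00000044786, -1.03 ± 0.20) fell. Among cell type genes, Aqp5 (ENSMUSG00000044217, -2.34 ± 0.40), the water channel of acinar cells, Tfcp2l1 (-1.26 ± 0.25) and the basal regulator Trp63 (ENSMUSG00000022510, -0.79 ± 0.15) were lower. The cornified envelope genes Lor (ENSMUSG00000043165, 2.64 ± 0.48) and Ivl (ENSMUSG00000049128, 0.92 ± 0.20) with Krt16 (1.94 ± 0.39) were higher. Large changes outside these lists were those of Apoe (-3.35 ± 0.49), the clock output gene Dbp (ENSMUSG00000059824, -2.81 ± 0.34), Hey1 (-2.80 ± 0.36), Col4a4 (-2.78 ± 0.39) and Selenbp1 (ENSMUSG00000068874, -2.67 ± 0.30), all lower, and the protease inhibitor Stfa2 (ENSMUSG00000022902, 4.43 ± 0.52), higher.

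Each had an adjusted p of 0.00806 or less by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment; of 10529 genes tested, 415 rose and 460 fell. Adjusted over the list alone, 34 interferon, 14 p53 and 13 hypoxia genes were past. Their camera adjusted p was 5.4e-55, 1.1e-05 and 2.1e-19 with the preset. With an estimated correlation it was 0.034, 0.013 and 0.013. Immediate early genes fell in 4 of 11 cases. For the immediate early genes, 6 were called adjusted over the list alone (camera adjusted p = 2e-06). Squamous genes had 6 higher of 18 (9 adjusted over the list alone; camera adjusted p = 0.00095, adjusted p = 0.45 with an estimated correlation). Total calls came to 438 without 15 Gy mouse 2, 524 without control mouse 3, 526 without control mouse 2 and 577 without control mouse 1. The squamous count was 3 without control mouse 2 or 3 or 15 Gy mouse 1 or 2. Squamous genes that fell numbered 1, 0 without control mouse 1 or 15 Gy mouse 2 or 3.

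Lower proton doses at day 2 gave a rise of interferon-stimulated genes in 25 of 35 (33 adjusted over the list alone, median 2.08; camera adjusted p = 8e-82) at 4 Gy, with Ifit1 (4.53 ± 0.53) and Isg15 (3.15 ± 0.52). At 7 Gy it was 30 of 35 (33 adjusted over the list alone, median 2.41; camera adjusted p = 1.5e-100), with Ifit1 (4.86 ± 0.53) and Isg15 (3.14 ± 0.53). Genes of G2 and mitosis fell in 3 of 30 cases at 7 Gy (6 with the replicate block, median -0.53, 16 adjusted over the list alone; camera adjusted p = 5.6e-14). By edgeR's quasi-likelihood test, 74 genes rose and 37 fell at 4 Gy (126 and 71 with the replicate block), and 171 rose and 139 fell at 7 Gy. Isg15 at 4 Gy was at 2.03 without 4 Gy mouse 2. The total at 4 Gy was 51 without control mouse 1 or 2, 54 without control mouse 3 and 177 without 7 Gy mouse 2. Calls at 7 Gy numbered 128 without control mouse 2, 133 without control mouse 3, 156 without control mouse 1 and 168 without 7 Gy mouse 1. The interferon count at 4 Gy was 15 without control mouse 3 and 16 without control mouse 1 or 2. The mitotic count at 7 Gy was 1 without control mouse 1, 2 or 3, 7 Gy mouse 1 or 15 Gy mouse 1, 2 or 3 and 8 without 4 Gy mouse 2.

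Between 4 and 15 Gy of protons at day 2, hypoxia and glycolysis genes had a median of -0.55, 11 of 16 lower adjusted over the list alone and 1 over all genes, 3 with the replicate block (camera adjusted p = 2.7e-16). Interferon-stimulated genes had a median of 0.19 (0 adjusted over the list alone; camera adjusted p = 0.0047, adjusted p = 0.75 with an estimated correlation). EdgeR's quasi-likelihood test called 6 genes higher and 7 lower, 19 and 42 with the replicate block, 7 and 19 with library size alone and 15 and 28 with DESeq2. All calls came to 0 without 4 Gy mouse 1 or 15 Gy mouse 2, 1 without 15 Gy mouse 3, 3 without 4 Gy mouse 3, 7 without control mouse 3, 8 without 4 Gy mouse 2 and 55 without 7 Gy mouse 2. The hypoxia count was 0 without 4 Gy mouse 1 or 15 Gy mouse 2 or 3, 2 without 15 Gy mouse 1 and 4 without 7 Gy mouse 2.

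The largest response followed 15 Gy of protons at day 6. Interferon-stimulated genes rose in 38 of 39 cases, with a median of 3.71, including Ifit1 (5.47 ± 0.33), Isg15 (4.41 ± 0.38), Ifit3 (7.26 ± 0.30), Ifit3b (7.92 ± 0.41) and Oasl2 (4.60 ± 0.20), Ifi44 (ENSMUSG00000028037, 4.05 ± 0.19) and Irf7 (3.89 ± 0.18). From a few control counts at most, Oas2 (ENSMUSG00000032690, at least 16.5-fold), Apol9a (ENSMUSG00000057346, 212-fold, counting interval 37.8 to 8.4e+03) and the immunity-related GTPase Iigp1 (ENSMUSG00000054072, 130-fold, counting interval 44.4 to 634) were higher. MHC class I genes rose in 11 of 13 cases, with Tap1 (2.40 ± 0.16), H2-K1 (ENSMUSG00000061232, 1.28 ± 0.15) and H2-D1 (1.40 ± 0.18). Sensing genes rose in 6 of 13 cases and fell in 1. Higher were Ifi204 (2.56 ± 0.22) and Tlr3 (1.44 ± 0.21) and Samhd1 (ENSMUSG00000027639, 0.96 ± 0.18), which degrades nucleotides. Targets of p53 rose in 18 of 40 cases and fell in 3: Mdm2 (1.45 ± 0.20) and Ccng1 (0.94 ± 0.13) and the repair nuclease Ercc5 (ENSMUSG00000026048, 1.17 ± 0.17) rose, the kinase Plk3 (ENSMUSG00000028680, -1.43 ± 0.20) fell. Hypoxia and glycolysis genes fell in 13 of 15 cases, with a median of -1.41. Ndrg1 (-2.71 ± 0.22) and Egln3 (-2.50 ± 0.24) fell, as did the kinase Pdk1 (ENSMUSG00000006494, -1.92 ± 0.18), which turns pyruvate away from mitochondria, and Slc2a1 (-1.41 ± 0.13). The carbonic anhydrase Car9 (ENSMUSG00000028463, -3.50 ± 0.35) was lower outside the list. Squamous genes fell in 11 of 15 cases, including Krt13 (-3.33 ± 0.31), Krtdap (-3.88 ± 0.39) and Krt6b (-2.68 ± 0.47). Cholesterol synthesis fell in 14 of 18, including Hmgcs1 (ENSMUSG00000093930, -1.03 ± 0.16) and Insig1 (ENSMUSG00000045294, -1.97 ± 0.31).

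Members of other lists changed at this dose and day. S phase genes fell in 13 of 31 cases, including Dut (ENSMUSG00000027203, -1.07 ± 0.17), Tipin (ENSMUSG00000032397, -0.91 ± 0.16), Pcna (ENSMUSG00000027342, -0.70 ± 0.14) and Uhrf1 (ENSMUSG00000001228, -1.35 ± 0.28), and those of G2 and mitosis in 6 of 30. Of the mitotic genes, Ccna2 (ENSMUSG00000027715, -1.44 ± 0.29), Cdk1 (ENSMUSG00000019942, -1.33 ± 0.28) and Aurkb (ENSMUSG00000020897, -1.70 ± 0.38) were lower. Secreted inflammatory factors had 2 higher and 10 lower of 27: Ccl5 (4.69 ± 0.36) rose, while the cytokine Il1a (ENSMUSG00000027399, -1.83 ± 0.17) and the chemokine Cxcl2 (ENSMUSG00000058427, -1.33 ± 0.20) fell. NRF2 targets fell in 8 of 15 cases, with Nqo1 (ENSMUSG00000003849, -1.77 ± 0.22) and Gclm (ENSMUSG00000028124, -0.94 ± 0.13). In the ATF4 list Nupr1 (ENSMUSG00000030717, 1.28 ± 0.13) rose and Shmt2 (ENSMUSG00000025403, -1.69 ± 0.17), Slc3a2 (ENSMUSG00000010095, -1.27 ± 0.14) and Vldlr (ENSMUSG00000024924, -1.45 ± 0.23) fell. Of basal duct genes Trp63 (-1.46 ± 0.19), Krt5 (ENSMUSG00000061527, -0.94 ± 0.13) and Krt14 (ENSMUSG00000045545, -0.96 ± 0.16) fell and the integrin Itga3 (ENSMUSG00000001507, 0.76 ± 0.16) rose. Luminal keratins split, Krt18 (ENSMUSG00000023043, 1.18 ± 0.17) rising and Krt19 (ENSMUSG00000020911, -0.92 ± 0.18) falling, and of the acinar genes Aqp5 (-2.05 ± 0.54) and Pip (ENSMUSG00000058499, -3.71 ± 0.79) fell while Chrm3 (1.44 ± 0.24) rose. Aqp5 was at -3.22 without 15 Gy mouse 2. Immediate early genes fell in 6 of 11 cases, with Ier2 (-1.35 ± 0.23) and Zfp36 (-1.26 ± 0.25).

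All genes named for this comparison had an adjusted p of 0.0107 or less by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment; of 10810 genes tested, 1184 rose and 1427 fell, or 1947 and 925 with library size alone, which shifted the median of all genes by 0.15. Adjusted over the list alone, 38 interferon, 11 MHC class I, 7 sensing and 13 hypoxia genes were called. Their camera adjusted p was 1.5e-142, 4.4e-13, 0.00096 and 3.4e-20 with the preset. With an estimated correlation it was 0.0011, 0.016, 0.034 and 0.016. For the p53 targets, 24 were called adjusted over the list alone (camera adjusted p = 2.5e-05, adjusted p = 0.18 with an estimated correlation). In the squamous list, 12 passed adjusted over the list alone (camera adjusted p = 9.1e-08, adjusted p = 0.14 with an estimated correlation). In cholesterol synthesis, 15 passed adjusted over the list alone (camera adjusted p = 6.1e-08, adjusted p = 0.055 with an estimated correlation). For S phase, 14 were called adjusted over the list alone (camera adjusted p = 6e-05, adjusted p = 0.37 with an estimated correlation). For G2 and mitosis, 6 were called adjusted over the list alone (camera adjusted p = 0.0011, adjusted p = 0.61 with an estimated correlation). For the inflammatory factors, 11 were called adjusted over the list alone (camera adjusted p = 0.0027, adjusted p = 0.27 with an estimated correlation). For the NRF2 targets, 10 were called adjusted over the list alone (camera adjusted p = 0.00068, adjusted p = 0.08 with an estimated correlation). In the immediate early genes, 6 passed adjusted over the list alone (camera adjusted p = 0.0092, adjusted p = 0.38 with an estimated correlation). Reads outside genes made up 10.2 to 10.8% in these libraries and 8.74 to 9.6% in their controls, with gene counts of 2806333 to 3225080 against 1812349 to 2244980, TMM factors of 1.01 to 1.05 against 0.895 to 0.946 and 28 to 31.1% against 33.3 to 37% of counts in the 50 most abundant genes; by chance 10% of measures part 3 libraries from 3. Mouse 2 had 59.9 CPM of Mki67 at this dose, against 6.34 and 15.5 in mouse 1 and mouse 3. The G2 and mitosis count was 17 without 15 Gy mouse 2. The S phase count was 6 without control mouse 2. The NRF2 count was 5 without control mouse 2. The sensing count was 3 without control mouse 3. The p53 targets that fell numbered 1 without control mouse 2 or 3 or 15 Gy mouse 2 and 5 without 15 Gy mouse 1, and the sensing genes 0 without control mouse 3 or 15 Gy mouse 2 or 3. Inflammatory factors that rose numbered 4 without 15 Gy mouse 3.

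Further lists were counted at 15 Gy of protons, day 6. Kinase inhibitors had 3 higher and 3 lower of 7 (3 and 3 adjusted over the list alone, median -0.26, camera adjusted p = 0.99). Their median and camera differed in sign. The ATF4 list had 2 higher and 7 lower of 17 (2 and 8 adjusted over the list alone, median -0.41, camera adjusted p = 0.062). Basal duct genes had 1 higher and 6 lower of 13 (1 and 6 adjusted over the list alone, median -0.23, camera adjusted p = 0.05). Nuclear proteins lost in senescence had 0 higher and 4 lower of 8 (0 and 4 adjusted over the list alone, median -0.42, camera adjusted p = 0.082). Homologous recombination genes had 0 higher and 2 lower of 11 (0 and 2 adjusted over the list alone, median -0.41, camera adjusted p = 0.12). End joining genes had 1 higher and 0 lower of 12 (1 and 0 adjusted over the list alone, median -0.13, camera adjusted p = 0.74). Their median was negative, their mean -0.01 and camera's direction higher. Luminal duct genes had 2 higher and 2 lower of 11 (2 and 2 adjusted over the list alone, median 0.03, camera adjusted p = 0.71). With the replicate block 1 luminal gene was higher. Myoepithelial genes had 1 higher and 0 lower of 4 (1 and 0 adjusted over the list alone, median 0.22, camera adjusted p = 0.51). The nuclear protein count was 1 without control mouse 2 or 15 Gy mouse 3. Basal duct genes that rose numbered 2 without 15 Gy mouse 1. Kinase inhibitors that rose numbered 1 without control mouse 2 or 3 or 15 Gy mouse 1, and those that fell 0 without 15 Gy mouse 3 and 1 without control mouse 1, 2 or 3 or 15 Gy mouse 1. Lower recombination genes numbered 1 without control mouse 2 or 3 or 15 Gy mouse 3, and higher luminal genes 1 without control mouse 1, 2 or 3 or 15 Gy mouse 3.

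Stem cell and Wnt target genes had 0 higher and 2 lower of 11 (0 and 2 adjusted over the list alone, median -0.17, camera adjusted p = 0.34). YAP targets had 2 higher and 4 lower of 14 (2 and 5 adjusted over the list alone, median 0.00, camera adjusted p = 0.74). TGF-beta and matrix genes had 0 higher and 3 lower of 17 (0 and 3 adjusted over the list alone, median 0.03, camera adjusted p = 0.43). The means of the YAP and TGF-beta lists were -0.39 and -0.19, and camera's direction was lower for both, against medians above 0. Heat shock genes had 1 higher and 3 lower of 10 (2 and 4 adjusted over the list alone, median -0.12, camera adjusted p = 0.76). Their median was 0.04 with library size alone. Mitochondrially encoded mRNAs had 0 higher and 1 lower of 7 (0 and 1 adjusted over the list alone, median -0.24, camera adjusted p = 0.51). Acinar markers had 1 higher and 2 lower of 3 (1 and 2 adjusted over the list alone, median -2.05, camera adjusted p = 0.51). Endothelial markers had 0 higher and 1 lower of 2 (0 and 1 adjusted over the list alone). With the replicate block 0 endothelial markers were lower. Immune cell markers had 0 higher and 0 lower of 1 (0 and 0 adjusted over the list alone). No granular duct or fibroblast marker passed the count filter in the proton series at day 6. Without that filter the fibroblast marker Postn (ENSMUSG00000027750) was lower at 7 and 15 Gy (adjusted p = 0.00037 and 0.00398 in edgeR). Counts at 0, 7 and 15 Gy were 24, 5 and 7. Pdgfra of that list, with 0, 6 and 5, was not called, so Postn does not speak for it. Leaving out any library but control mouse 1 or 3 also let Postn in. It was then lower at 15 Gy in 10 of 10 fits (-2.88 to -2.25, adjusted p of 0.0496 or less in edgeR), at 7 Gy in 9 and at 4 Gy in 0. After photons at day 6, Postn was lower at 7 Gy (-1.95 ± 0.49, adjusted p = 0.0456 in edgeR), but not without control mouse 2 or 3, 4 Gy mouse 1 or 2, 7 Gy mouse 1 or 2 or 15 Gy mouse 1 (0.0639 to 0.223). At 4 and 15 Gy it was at -2.08 ± 0.54 and -1.47 ± 0.46 (adjusted p = 0.103 and 0.0839 in edgeR). At 15 Gy it passed unfiltered, in a single fit, with the block (0.0019) and without control mouse 1 (-1.82) or 15 Gy mouse 3 (-2.23). Adjusted over the list alone it passed at 4, 7 and 15 Gy of photons, but as the only measured member its p was then not adjusted at all. Over all libraries the acinar markers reached 43 CPM, mostly Chrm3, the granular duct markers 3.82, the fibroblast markers 4.66, the endothelial markers 23.1 and the immune markers 6.05. The YAP count was 2 without control mouse 2 or 3 or 15 Gy mouse 2 or 3. YAP targets that rose numbered 1 without control mouse 2 or 15 Gy mouse 1 or 3. TGF-beta genes that rose numbered 1 without 15 Gy mouse 2 and 2 without 15 Gy mouse 1. Stem cell genes that rose numbered 1 without 15 Gy mouse 1, and those that fell 1 without control mouse 2 or 3. Higher heat shock genes numbered 3 without 15 Gy mouse 1. Higher mitochondrial mRNAs numbered 1 without 15 Gy mouse 1, and lower ones 0 without control mouse 2 or 15 Gy mouse 1. Lower endothelial markers numbered 0 without control mouse 1 or 3, 4 Gy mouse 3, 7 Gy mouse 1 or 2 or 15 Gy mouse 1 or 3.

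At the lower proton doses of day 6, interferon-stimulated genes rose in 36 of 39 (38 adjusted over the list alone, median 2.78, or 2.7 with near-absent genes at their bound; camera adjusted p = 4.1e-247) at 4 Gy. The count was 38 of 39 (39 adjusted over the list alone, median 3.65; camera adjusted p = 9.7e-201) at 7 Gy. Ifit1 (4.43 ± 0.33) and Isg15 (3.48 ± 0.38) rose at 4 Gy. At 7 Gy Ifit1 (5.47 ± 0.33), Isg15 (4.18 ± 0.38), Mdm2 (1.42 ± 0.20) and Krt14 (-1.03 ± 0.16) changed. MHC class I genes rose in 6 of 13 (10 adjusted over the list alone; camera adjusted p = 1e-23) at 4 Gy. Hypoxia genes fell in 13 of 15 (14 adjusted over the list alone; camera adjusted p = 5.4e-21) at 7 Gy, and squamous genes in 11 of 15 (12 adjusted over the list alone; camera adjusted p = 4.8e-12, adjusted p = 0.05 with an estimated correlation). By edgeR's quasi-likelihood test, 122 genes rose and 47 fell at 4 Gy, or 181 and 27 with library size alone, and 594 rose and 713 fell at 7 Gy, or 1400 and 380, with shifts of 0.11 and 0.19 in the median of all genes. Total calls at 4 Gy came to 103 without control mouse 2 and 104 without 4 Gy mouse 3. The total at 7 Gy was 679 without control mouse 2 or 7 Gy mouse 2 and 868 without control mouse 3.

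From 4 to 15 Gy of protons at day 6, interferon-stimulated genes rose further in 25 of 39 cases, with a median of 0.97; Rsad2 (1.91 ± 0.21), Ifit3b (1.86 ± 0.21), Ifit3 (1.80 ± 0.17) and Gbp9 (ENSMUSG00000029298, 2.08 ± 0.39) were among them. Hypoxia and glycolysis genes fell in 10 of 15 (13 adjusted over the list alone; camera adjusted p = 3e-18). Cholesterol synthesis fell in 9 of 18 (13 adjusted over the list alone; camera adjusted p = 1.6e-10). The matrix protein Thbs2 (ENSMUSG00000023885, -3.02 ± 0.57) and Krtdap (-2.83 ± 0.41) were lower. Their adjusted p was 0.00769 or less by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and the interferon list passed (33 adjusted over the list alone; camera adjusted p = 6.1e-38). Of all genes, 284 were higher and 440 lower, or 338 and 312 with library size alone. Calls numbered 225 without 4 Gy mouse 2, 254 without 15 Gy mouse 3, 259 without 4 Gy mouse 3, 307 without 4 Gy mouse 1 and 1515 without 15 Gy mouse 1. Called interferon genes numbered 15 without 4 Gy mouse 2 and 16 without 4 Gy mouse 1. Called cholesterol genes numbered 4 without 4 Gy mouse 1 or 3 and 5 without 15 Gy mouse 3.

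**Figure D2:**
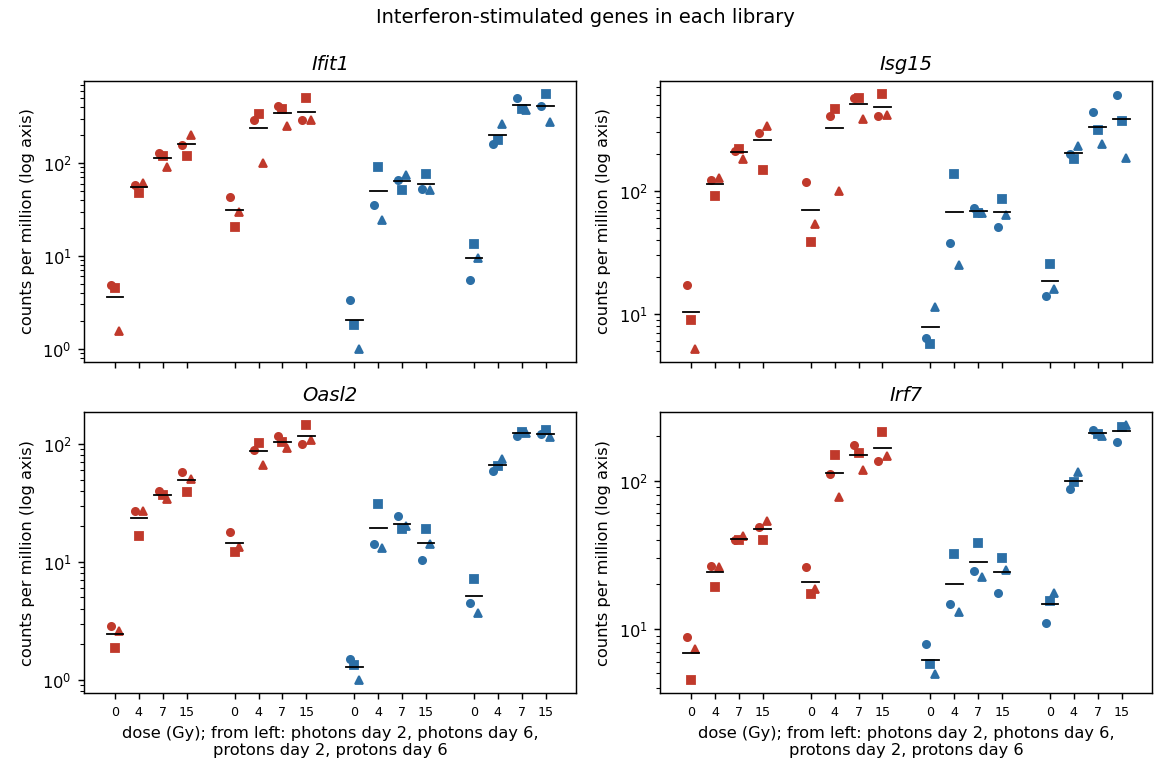
CPM (log axis) of 4 interferon-stimulated genes in each of the 48 libraries, by dose (horizontal axis, Gy), with photons in red and protons in blue; circles, squares and triangles are mouse 1, 2 and 3 and black lines are group means of 3 libraries. In all 4 genes the means of the irradiated groups lay above those of their controls.

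**Figure D3:**
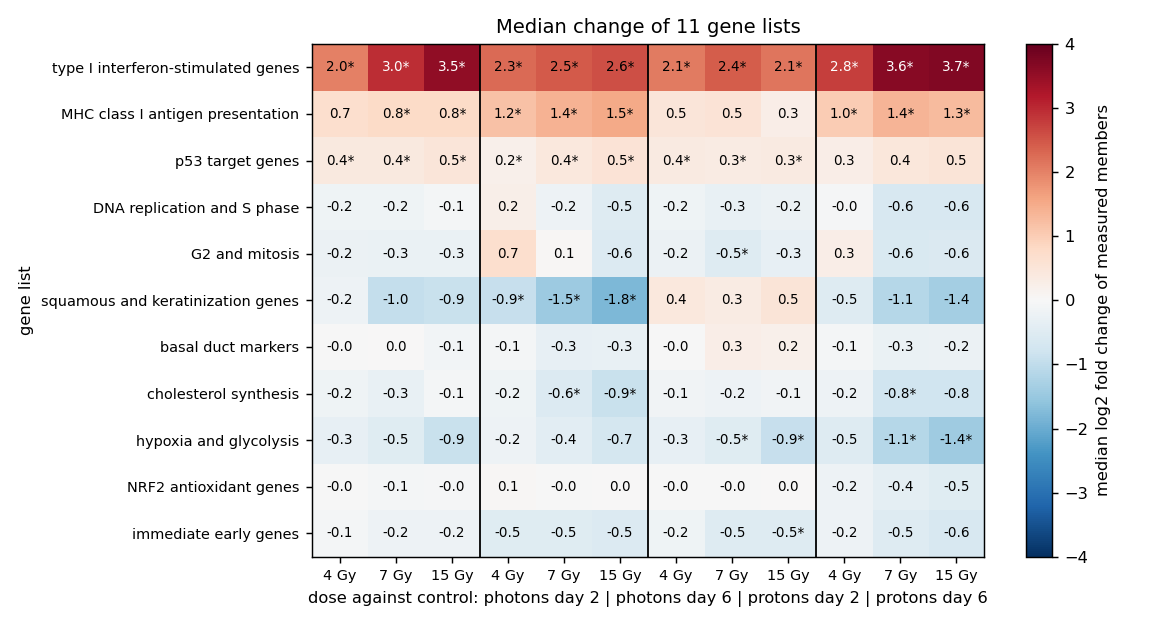
Median log2 fold change against the matching control (color, red higher and blue lower; number in each cell) for 11 gene lists (vertical axis) at each dose, day and radiation type (horizontal axis), 3 libraries per group; an asterisk marks a camera adjusted p under 0.05 with an estimated correlation. The interferon list had the highest median in every column, up to 3.71 at 15 Gy of protons, day 6.

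Whether protons and photons acted on different genes was tested as the difference between their effects. At 15 Gy, day 6, the proton effect exceeded the photon effect in 10 of 39 interferon-stimulated genes, with a median difference of 1.27. The guidance cue gene Sema3d (ENSMUSG00000040254, 3.12 ± 0.44) was higher, from 6.19 ± 1.94 (SD, n = 3) to 23.7 ± 4.2 CPM after protons and from 10.9 ± 2.42 to 4.89 ± 0.264 after photons. The amino acid carrier Slc7a5 (ENSMUSG00000040010, -2.66 ± 0.49) went from 134 ± 56.9 to 17.1 ± 10.5 after protons and from 42.4 ± 11.8 to 36.7 ± 8.56 after photons, and the adaptor Apba3 (ENSMUSG00000004931, -3.86 ± 0.69) from 35.8 ± 16.7 to 4.01 ± 2.98 and from 4.51 ± 4.52 to 8.77 ± 2.61. NRF2 targets had 5 of 15 members lower (median -0.42) and hypoxia genes 3 of 16 (median -0.85). The 3 genes had an adjusted p of 0.00926 or less by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and all calls came to 289 higher and 210 lower, or 492 and 95 with library size alone. In the interferon list, 24 passed adjusted over the list alone (camera adjusted p = 6.3e-13, adjusted p = 0.41 with an estimated correlation). In the NRF2 targets, 6 passed adjusted over the list alone (camera adjusted p = 0.00091, adjusted p = 0.26 with an estimated correlation). In the hypoxia list, 6 passed adjusted over the list alone (camera adjusted p = 3.2e-06, adjusted p = 0.41 with an estimated correlation). With the replicate block 5 hypoxia genes were lower. All calls came to 41 without photon control mouse 1, 97 without photon 15 Gy mouse 1, 102 without proton control mouse 3, 124 without proton control mouse 2, 145 without photon 15 Gy mouse 3, 186 without photon control mouse 2, 219 without proton 15 Gy mouse 2, 252 without proton 15 Gy mouse 3, 892 without photon control mouse 3, 1060 without photon 4 Gy mouse 3 and 1254 without proton 15 Gy mouse 1. Members called in the interferon list numbered 0 without photon control mouse 1, 4 without photon 15 Gy mouse 1 or 3, proton control mouse 3 or proton 15 Gy mouse 2, 6 without photon control mouse 2 or proton control mouse 2 and 16 without photon control mouse 3. Called NRF2 genes numbered 0 without photon control mouse 1, photon 15 Gy mouse 1 or proton control mouse 2, 1 without photon control mouse 2, proton control mouse 3 or proton 15 Gy mouse 3, 2 without photon 15 Gy mouse 3 and 3 without proton 15 Gy mouse 2. Members called in the hypoxia list numbered 1 without photon control mouse 1 and 7 without photon control mouse 3.

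At the other doses and days, lists were compared as well, and squamous genes had a median of 1.47 at 15 Gy, day 2 (14 of 20 adjusted over the list alone, 9 over all genes with the replicate block; camera adjusted p = 1.3e-23, adjusted p = 0.068 with an estimated correlation). The median was 1.23 at 7 Gy (8 adjusted over the list alone, 8 over all genes with the block; camera adjusted p = 1.1e-11, adjusted p = 0.43 with an estimated correlation). Interferon-stimulated genes had a median difference of -0.97 at 15 Gy, day 2 (7 adjusted over the list alone; camera adjusted p = 4.1e-17, adjusted p = 0.15 with an estimated correlation). At 7 Gy, day 6, it was 1.24 (17 of 39 adjusted over the list alone; camera adjusted p = 8e-23, adjusted p = 0.12 with an estimated correlation). Over all genes edgeR's quasi-likelihood test called 0 at 4, 7 and 15 Gy of day 2 and at 4 and 7 Gy of day 6, with 311, 1018, 571, 454 and 1145 genes at an unadjusted p under 0.05; DESeq2 called 0, 0, 1, 0 and 25. With the replicate block, 35 were higher at 7 Gy, day 2, and 53 higher and 5 lower at 15 Gy, day 2. Total calls at 15 Gy, day 2, came to 1 without photon 4 Gy mouse 2. The total at 7 Gy, day 6, was 1 without photon 15 Gy mouse 2 or proton control mouse 1 and 10 without photon control mouse 3. The lists of changed genes overlapped: at 15 Gy, day 2, 178 genes rose after both radiation types (11 from independent lists, Fisher's exact p = 1.7e-195) and 144 fell (11, exact p = 7.4e-137). At day 6, 183 rose (30, exact p = 6.2e-114) and 173 fell (38, exact p = 1.6e-81). Of the genes called after both at 15 Gy, 0 went opposite ways on either day, and these comparisons share no library.

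**Figure D4:**
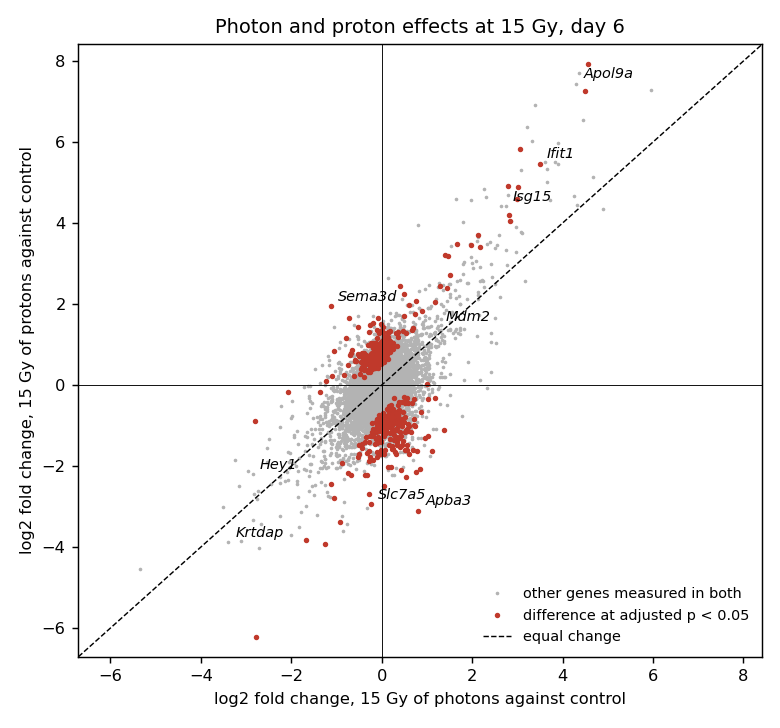
Each point is a gene measured after both radiation types, with its log2 fold change at 15 Gy, day 6, against control after photons (horizontal axis) and after protons (vertical axis), 3 libraries per group; red points are the genes whose difference had an adjusted p under 0.05 and the dashed line is equal change. Most red points lie farther from 0 along the proton axis, with Sema3d above the line and Apba3 and Slc7a5 below it.

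How the effect of 15 Gy changed between the days was tested in the same way. After protons, the effect on squamous genes was lower at day 6 than at day 2 in 9 of 18 cases, with a median difference of -1.84 (11 adjusted over the list alone; camera adjusted p = 4.8e-18); against control their median was 0.53 at day 2 and -1.36 at day 6. The semaphorin gene Sema3e (ENSMUSG00000063531, 2.79 ± 0.30) was higher in its day 6 effect, and Nat8l (ENSMUSG00000048142, -4.74 ± 0.67) and Krt14 (-1.28 ± 0.25) lower. Cholesterol synthesis was lower in 6 of 18 (11 adjusted over the list alone; camera adjusted p = 5.1e-09). By edgeR's quasi-likelihood test, 117 genes were higher and 178 lower, or 252 and 127 with library size alone, which shifted the median of all genes by 0.11. The adjusted p of the 3 genes was 0.00564 or less after Benjamini-Hochberg adjustment in edgeR. Calls numbered 94 without control mouse 2 of day 2, 125 without control mouse 2 of day 6, 127 without 15 Gy mouse 1 or 2 of day 2, 177 without control mouse 3 of day 2, 195 without control mouse 3 of day 6, 454 without 7 Gy mouse 2 of day 2, 523 without 4 Gy mouse 2 of day 2 and 590 without 15 Gy mouse 1 of day 6. Members called in the cholesterol list numbered 3 without control mouse 2 of day 2 or 15 Gy mouse 2 of day 2. After photons, Aqp4 (ENSMUSG00000024411, -2.46 ± 0.34), a water channel, Fos (ENSMUSG00000021250, -2.22 ± 0.38) and Pcdh18 (ENSMUSG00000037892, -1.90 ± 0.28) and the hyaluronan synthase Has2 (ENSMUSG00000022367, -1.89 ± 0.29) were lower in their day 6 effect (adjusted p of 0.00967 or less by the same test). The test called 2 genes higher and 10 lower. All calls came to 5 without 15 Gy mouse 2 of day 2, 7 without control mouse 2 of day 2, 22 without 4 Gy mouse 3 of day 6 and 50 without control mouse 3 of day 2.

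Culture time alone was followed in the unirradiated organoids, of which day 6 was compared with day 2. In the photon series, genes of G2 and mitosis fell in 30 of 30 cases, with a median of -1.99, and Mki67 (-1.93 ± 0.34) and Lmnb1 (ENSMUSG00000024590, -0.88 ± 0.19) fell while Cdkn1a (0.80 ± 0.17) rose. Squamous genes fell in 13 of 18, basal duct genes in 9 of 13 (Krt14 (-1.75 ± 0.26)) and cholesterol synthesis in 12 of 18. The iron-binding secretory protein Ltf (ENSMUSG00000032496, 5.85 ± 0.41) and the oxidase subunit Cybb (ENSMUSG00000015340, 6.75 ± 0.40) rose, as did Ifit1 (2.99 ± 0.47) and Isg15 (2.64 ± 0.49) among 25 of 39 interferon-stimulated genes (median 1.82, or 1.67 with near-absent genes at their bound). Of 3 measured immune cell markers 2 were higher from no counts at day 2, Itgam (ENSMUSG00000030786, at least 11-fold) and Lyz2 (ENSMUSG00000069516, at least 8.97-fold), with a median of 6.53, or 3.17 with both at their bound (2 adjusted over the list alone; camera adjusted p = 0.046, adjusted p = 0.14 with an estimated correlation). Lower were the desmosome gene Dsg1b (ENSMUSG00000061928, -5.39 ± 0.83), the protease inhibitor Serpinb3a (ENSMUSG00000044594, -5.09 ± 0.47) and the fatty acid carrier Fabp4 (ENSMUSG00000062515, -4.94 ± 0.56). In the proton series, 29 of 30 genes of G2 and mitosis fell (median -1.37), with Mki67 (-1.87 ± 0.40), and squamous genes fell in 14 of 18, basal duct genes in 8 of 13 (Krt14 (-1.46 ± 0.18); 1 rose, 2 without 7 Gy mouse 3 of day 6) and cholesterol synthesis in 14 of 18. Ltf (7.26 ± 0.30) rose, and Cybb (at least 44.2-fold) was higher. Secreted inflammatory factors rose in 18 of 28 and fell in 4, and ATF4 genes rose in 10 of 17 and fell in 1. Dsg1b (-5.97 ± 0.61) fell, and with no count at day 6 Gsdmc (ENSMUSG00000079025, at least 59.3-fold) and Lypd5 (ENSMUSG00000030484, at least 21-fold) were lower. 

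By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 724 genes rose and 982 fell in the photon series, the named genes at an adjusted p of 0.00267 or less. Total calls came to 1119 without control mouse 1 of day 6. In G2 and mitosis, 30 passed adjusted over the list alone (camera adjusted p = 9.1e-46). For basal duct genes, 10 were called adjusted over the list alone (camera adjusted p = 1.1e-06). Of cholesterol synthesis, 17 were past adjusted over the list alone (camera adjusted p = 1.6e-13). Of the squamous list, 16 were past adjusted over the list alone (camera adjusted p = 1.4e-13, adjusted p = 0.059 with an estimated correlation). Of the interferon list, 27 were past adjusted over the list alone (camera adjusted p = 9.3e-20, adjusted p = 0.059 with an estimated correlation). The interferon count was 16 without control mouse 1 of day 6. In the proton series, 925 genes rose and 1023 fell by the same test, the named genes at an adjusted p of 0.0013 or less. Of G2 and mitosis, 29 were past adjusted over the list alone (camera adjusted p = 5e-24). For the squamous list, 15 were called adjusted over the list alone (camera adjusted p = 1.4e-20). In basal duct genes, 10 passed adjusted over the list alone (camera adjusted p = 2.7e-06). For cholesterol synthesis, 15 were called adjusted over the list alone (camera adjusted p = 4.6e-10). In the inflammatory factors, 20 passed adjusted over the list alone (camera adjusted p = 3.9e-22). For the ATF4 list, 11 were called adjusted over the list alone (camera adjusted p = 3.8e-09). Interferon-stimulated genes rose in 11 of 39 (13 adjusted over the list alone; camera adjusted p = 7.5e-06, adjusted p = 0.32 with an estimated correlation). Called interferon genes numbered 5 without control mouse 2 of day 6 and 6 without control mouse 1, 2 or 3 of day 2.

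Interferon transcripts themselves were nearly absent: the 21 interferon ligand genes held 18 counts over the 48 libraries, in 5 of the genes, and Ifnb1 held 3. Reads of near-identical genes, such as Ifit3 and Ifit3b, Oas2 and other Oas genes, the H2 heavy chains, Apol9a, Iigp1 and Stfa2, could be split or shared by the counting, and whether strand was used is not given in the sources used here, so their values are uncertain.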

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

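The leukocyte test, the cycling tests and both interferon tests were chosen after their results were seen; the depth, length and matched-list tests and the splits were planned, and thinning to the lowest total and the left-out libraries of the cycling tests were added last. At 15 Gy, day 6, 499 genes differed between the proton and the photon effect. After thinning all 24 libraries to the lowest total, 314409 counts, calls fell to 0 to 22. The 416 to 427 called genes still measured had a slope of 1.01 (SD 0.019) on their full differences. Thinning keeps expected differences, so the slope cannot test depth. With 23 libraries thinned to 1800000 counts and the lowest as it was, the slope was 1 (SD 0.0033) and calls 305 to 406. Over all genes the difference followed gene length weakly (Spearman correlation 0.13), and removing that trend left a slope of 0.98 (SD 0.0032). A trend this weak can take little from genes picked for large differences, so the slope does not decide on length. The median length was 51.2 kb in genes higher after protons, 21.3 kb in genes lower and 23.6 kb in all. For the interferon-stimulated genes, camera with an estimated correlation gave an adjusted p of 0.41, 35 of 39 were higher in the photon than in the proton controls, and their median control difference, 0.871, enters the median difference of effects, 1.27, by construction, so its share of 0.685 (SE 0.11 over genes) does not decide whether a higher photon baseline is the cause; the levels at 15 Gy differed by 0.508 (SE 0.039 over genes). The day of irradiation cannot be told apart from the radiation type. Unequal depth, gene length, the higher photon baseline and a biological difference stay open.

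In unirradiated photon organoids Cybb and Ltf rose from day 2 to day 6, with 1196 and 4645 counts at day 6. Leukocytes, which express both, would bring their other abundant transcripts. The 12 leukocyte markers summed to 42 counts, 3.51% of the counts of Cybb, 35 of them from Lyz2, with 0 for Ptprc, Tyrobp, Fcer1g and Laptm5, which argues against leukocytes as the main source. The leukocyte integrin Itgam, not among the 12, had 43 counts and rose with Lyz2 from 0, so a small share of such cells stays open. Cell types within the gland were not tested.

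Hypoxia and glycolysis genes were lower at 15 Gy, with medians of -0.896, -0.718, -0.907 and -1.41 for photons at days 2 and 6 and protons at days 2 and 6. Of 10000 random lists matched on expression level, 0 had a median as low in any of these comparisons, which argues against a trend with expression. At day 2 the median of mitotic genes exceeded that of hypoxia genes by 0.615 (SE 0.14) for photons and 0.587 (SE 0.19) for protons. Both passed 2 SE with each library left out. As these SE span genes, not mice, this argues only weakly against fewer cycling cells as the whole cause there. The day 6 difference was 0.165 (SE 0.18) for photons and 0.818 (SE 0.28) for protons. It was 0.376 (SE 0.28) without 15 Gy of protons, mouse 2. Fewer cycling cells cannot be told apart there from a separate fall of hypoxia genes. Culture density and oxygen were not tested.

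Between the days, the effect of 15 Gy differed in 12 genes after photons and in 295 after protons. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05, and the real split was 1 of the 10 with a count as large in each of 18 comparisons. The highest other count was 495 against 547 for 15 Gy of photons at day 2, 135 against 2611 for 15 Gy of protons at day 6, 1 against 13 for 15 against 4 Gy of protons at day 2 and 179 against 1706 for the photon controls over time, and 0 in the others. The 495 arose in the series whose control of mouse 3 stands apart, but which mouse that split exchanged was not kept. The 495, 135 and 179 came from the 3 other splits that, like the real split, put each mouse on both sides, and the remaining splits of these comparisons gave 0. For differences of effects 40 splits were drawn. A count as large as the real one came from 5 of them for the 499 genes, with a highest other count of 1145, from 11 for the 12 genes, with 1282, and from 7 for the 295 genes, with 1963, so chance is not excluded for any of these 3. For the comparisons with 0 calls the 40 of 40 was fixed, since any split gives at least 0; their splits had highest other counts of 1244, 28 and 635 for 4, 7 and 15 Gy at day 2 and 1400 and 905 for 4 and 7 Gy at day 6. Splits that call several times the real count point to a structure of the samples, which here includes the radiation types or days themselves, since these splits mix them.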

How the results depend on the processing

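Leaving out the libraries that stand apart was chosen after seeing the data, and all other alternatives before. No gene named by the rule reversed direction. The side with more calls did change; higher and lower calls were then as follows for 7 Gy of photons, day 2 (169 and 186 with the block), 15 Gy of photons, day 2 (431 and 633 unfiltered, 294 and 357 with the block, 377 and 379 in DESeq2, 612 and 680 without those libraries), 15 Gy of photons, day 6 (244 and 223 in DESeq2), 15 Gy of protons, day 2 (473 and 402 by library size, 471 and 433 in a single fit), 7 Gy of protons, day 6 (1400 and 380 by library size) and 15 Gy of protons, day 6 (1947 and 925 by library size, 1441 and 1378 unfiltered). So it was for 15 against 4 Gy of photons, day 2 (103 and 350 unfiltered), 15 against 4 Gy of protons, day 2 (7 and 5 in a single fit), 15 against 4 Gy of protons, day 6 (338 and 312 by library size), protons less photons at 15 Gy, day 6 (237 and 254 with DESeq2's size factors, 381 and 523 unfiltered, 308 and 310 in DESeq2), day 6 less day 2 after photons (81 and 64 unfiltered), day 6 less day 2 after protons (252 and 127 by library size) and photon controls over time (796 and 775 by library size). With 1 library left out it changed for 7 Gy of photons, day 2 (318 and 367 without control mouse 1), 15 Gy of photons, day 2 (302 and 338 without control mouse 1, 612 and 680 without control mouse 3, 293 and 295 without 4 Gy mouse 2), 15 Gy of photons, day 6 (202 and 176 without 15 Gy mouse 1, 146 and 125 without 15 Gy mouse 2, 230 and 198 without 15 Gy mouse 3) and 15 Gy of protons, day 2 (307 and 306 without 15 Gy mouse 3). The others were 7 Gy of protons, day 6 (345 and 334 without 7 Gy mouse 2), 15 against 4 Gy of protons, day 2 (1 and 0 without 15 Gy mouse 3), 15 against 4 Gy of protons, day 6 (133 and 121 without 15 Gy mouse 3) and protons less photons at 15 Gy, day 6 (441 and 451 without photon control mouse 3, 362 and 385 without proton control mouse 1, 576 and 678 without proton 15 Gy mouse 1). Without the low-count filter more genes were tested, and calls came to 264, 873 and 1064 for 4, 7 and 15 Gy of photons, day 2; 367, 566 and 991 for 4, 7 and 15 Gy of photons, day 6; 246 and 479 for 4 and 7 Gy of protons, day 2; 340 for 4 Gy of protons, day 6. Further counts were 453 and 269 for 15 against 4 Gy of photons, days 2 and 6; 140 and 1198 for 15 against 4 Gy of protons, days 2 and 6; 1, 148 and 122 for protons less photons at 4, 7 and 15 Gy, day 2; 18, 167 and 904 for protons less photons at 4, 7 and 15 Gy, day 6. It also gave 145 and 631 for day 6 less day 2 after photons and protons. DESeq2 gave 116 for 4 Gy of photons, day 2; 75 and 51 for 15 against 4 Gy of photons, days 2 and 6; 43 for 15 against 4 Gy of protons, day 2; 1 for protons less photons at 15 Gy, day 2. Next were 25 for protons less photons at 7 Gy, day 6; 44 and 506 for day 6 less day 2 after photons and protons. A single fit of all libraries gave 123, 610 and 1092 for 4, 7 and 15 Gy of photons, day 2; 71 and 69 for 15 against 4 Gy of photons, days 2 and 6; 2 for protons less photons at 15 Gy, day 2; 6 and 327 for protons less photons at 7 and 15 Gy, day 6. The last was 33 for day 6 less day 2 after photons. Library size alone gave 7 for 15 against 4 Gy of photons, day 2; 26 for 15 against 4 Gy of protons, day 2. Without the libraries that stand apart calls came to 1292 for 15 Gy of photons, day 2; 495 and 1025 for 7 and 15 Gy of photons, day 6; 88 and 64 for 15 against 4 Gy of photons, days 2 and 6; 1060 for protons less photons at 15 Gy, day 6. The last count was 228 for day 6 less day 2 after photons. The replicate block, pairing by mouse, gave 197 for 4 Gy of protons, day 2; 61 for 15 against 4 Gy of protons, day 2; 35 and 58 for protons less photons at 7 and 15 Gy, day 2. The block also moved 90 list counts by over 1.5 times; beside the changes given with their results, it changed no other call printed in the report. The cause of these changes was not tested, nor was it for the filter, which sets how many genes are tested. DESeq2's size factors and the stricter filter left each count of calls within 1.5 times. With each library left out in turn, calls at 4, 7 and 15 Gy of photons ran from 23 to 172, 132 to 685 and 252 to 1292 at day 2 and from 63 to 189, 166 to 495 and 271 to 1025 at day 6. For protons they ran from 51 to 177, 128 to 436 and 438 to 1206 at day 2 and from 103 to 251, 679 to 1680 and 1769 to 3128 at day 6. Between 15 and 4 Gy it was 0 to 88 and 1 to 64 for photons at days 2 and 6 and 0 to 55 and 225 to 1515 for protons. For protons less photons at 4, 7 and 15 Gy it was 0 to 0, 0 to 0 and 0 to 1 at day 2 and 0 to 0, 0 to 10 and 41 to 1254 at day 6. For day 6 less day 2 it was 5 to 50 after photons and 94 to 590 after protons, and for photon and proton controls over time 1119 to 2038 and 1435 to 2111. Of the 389 calls that the naming rule gave, 139 missed the threshold with at least 1 library left out, 250 did not, and 67 missed it under another alternative. Calls missed numbered 37 in the single fit, 24 in DESeq2, 23 with library size alone, 8 without the filter and 4 with the block. In simulated counts at the depth and spread of 15 Gy, day 6, 38% of log2 differences of 1 between proton and photon effects and 79% of differences of 2 were recovered. Of the 126 calls there, 9 were false. Depth was not separated from the number of libraries.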

Other observations

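Genes that changed at day 2 were followed to day 6. After 15 Gy of photons 144 genes rose on both days, against 6.8 from independent lists (Fisher's exact p = 2.9e-172), 75 fell on both, against 6.9 (exact p = 1.4e-58), and 4 went opposite ways. After 15 Gy of protons 207 rose on both days, against 43 (exact p = 1.2e-98), 264 fell, against 60 (exact p = 4e-120), and 17 went opposite ways. These pairs of comparisons share no library. Genes are not independent replicates, so these p-values describe the lists only.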
